A study of Homo sapiens with 10 samples.

How the data were processed

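The deposited values are probe set signal intensities on a linear scale, made by the authors with MAS5 in Affymetrix Expression Console, per the submitters' processing notes; the versions are not given in the sources used here. The values themselves show a 2% trimmed mean of about 500 on every array. Per the labels' protocols, RNA was amplified in 2 rounds with 1 of 2 kits before labelling, and which array had which kit is not stated. The labels attach the capture protocol to every sample. No detection calls were used here.

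The table held 54675 probe sets, 62 of them controls. A platform annotation named 1 gene for 41032, several for 1765 and none for 11721; symbols were updated through RefSeq for 40978 and kept for 54. Genes whose levels could help identify a person were left out, and HLA genes are left unnamed. Of the genes on the lists 47 had no usable probe set. The filter on dim genes, below, left out further members, and counts of list members are of those measured. Measured were 20 of 36 acinar, 16 of 27 islet, 4 of 15 intestinal epithelium and 3 of 9 red blood cell genes. Signals were taken as log2 after adding an offset of 28.84, the 20th percentile of all signals, so that fold changes of dim genes are understated. Each gene was represented by its probe set with the highest mean, passing over those with the suffix _x_at where the gene had another. Fold changes hold for that probe set, and other probe sets of the gene could differ in size. Genes under the 40th percentile of probe sets (log2 6.856) were left out, leaving 14570. No scaling was added to that of the authors.

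Tests used limma 3.58.1 in R 4.3.3 with a variance trend and Benjamini-Hochberg adjustment at 0.05. The LCM comparison and the difference of effects used group means over the 8 pancreatic arrays; the 3 preparations together and the comparisons of preparations used an additive fit of preparation and status over those 8; the ovarian comparison used all 10. Groups of 1 array are assumed to vary like the others. The bulk and brushing pairs have no test, and list medians there are set against 10000 random lists. Bounds and ranges of matched genes and random lists leave out 2.5% of the draws at either end. The 24 gene lists were tested with camera at a preset correlation of 0.01 and with an estimated one. With the latter 0 of 168 tests passed, against 78. That form takes its degrees of freedom from the residuals of the few arrays, so a failure there can come from their number alone. For the ductal list in captured cancer the estimated correlation was -0.0416, below the preset one. Yet its unadjusted camera p went from 5.93e-09 to 0.0239. Other lists had estimates above the preset one, islet in captured cancer at 0.712 among them, and there correlation can add to a failure. Agreement between preparations is Pearson's r across genes. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 handled tables and figures.

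The genes named, the lists, the designs and most alternatives were fixed before the data were examined. Named genes are the 12 highest and 12 lowest fold changes among genes past the threshold whose arrays do not overlap, 5 and 5 by statistic where none passed, 12 and 12 by difference for single pairs, and up to 4 members of each list. Alternatives covered scaling, offset, filter, probe sets, variance model, arrays in the fit and each array left out. A common noise floor, array weights and fits without both LCM cancer arrays were chosen after the data were seen, as was matching random lists on the LCM healthy level.

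The steps were tested on simulated data of 14570 genes with 200 changed. Each gene had its real mean, the same on every array, and a single fitted spread, the same in every group. In the data the replicates differed with an SD of 1.46 in LCM cancer, 1.04 in LCM healthy and 1.59 in the ovarian pair. The shares below leave out such unequal spreads and need not hold for the real arrays. For the LCM comparison, changes of 1, 2, 3 and 4 on the log2 scale were recovered in 0%, 4%, 40% and 78% of genes, and 10.3% of calls were false. For the 3 preparations together the shares were 0%, 30%, 84% and 100%, with 2.7% false. There the simulated change was the same in every preparation. In the data the effects had Pearson's r of 0.031 to 0.243 between preparations. The simulation leaves out such differences, which count as spread in the real fit, so real recovery can be lower. For the ovarian comparison they were 0%, 0%, 2% and 22%, with 14.3% false, and for the difference of effects 0% at every size.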

Results

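Gene expression was measured on 10 Affymetrix U133 Plus 2.0 arrays of human tissue. Pancreatic adenocarcinoma and adjacent tissue labelled healthy were each sampled by 3 preparations. Laser capture microdissection (LCM), which lifts chosen cells from a stained frozen section, gave 2 cancer and 2 healthy arrays. Bulk tissue gave 1 of each, and brushing of the duct, which collects cells of its lining, gave 1 of each. Bulk ovarian adenocarcinoma gave 2 arrays. Levels are log2 of the deposited signal plus an offset, and 14570 genes were tested. The number of arrays limits the precision. The labels do not say whether arrays came from separate donors, so p-values measure only the spread between these samples, which may be technical; captured regions of a group could share a donor, and p-values over them may then be too small.

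The LCM cancer arrays stood apart from the others before any comparison, and also from each other. Across genes, which are not independent replicates, Pearson's r of levels was 0.659 between the LCM cancer arrays and 0.877 between the LCM healthy arrays. LCM cancer replicate 1 had r of 0.678 and 0.705 with the LCM healthy arrays and 0.701 with bulk cancer. All of these lay above that with its own replicate. LCM healthy replicate 1 had r of 0.911 and 0.904 with the healthy and cancer brushings, also above that with its own replicate. Hybridization control transcripts, which are added in a fixed amount, had a geometric mean signal of 53110 on LCM cancer replicate 1 and 123700 on replicate 2. These were 24.7 and 57.5 times that of the brushing cancer array, the lowest, and the LCM healthy arrays stood at 4.71 and 13.6 times. The 20th percentile of signal was 55.7 and 62.5 on the LCM cancer arrays and lay between 13.8 and 38.5 on the other arrays. Ovarian replicate 1 differed in another way, with a ratio of 3-prime to 5-prime GAPDH signal of 1.77 against 12.1 to 46.9 on the others. The same ratio for ACTB was 69.8 and 105.9 on the cancer and healthy brushings and 27.3 and 33.6 on bulk pancreas. It was 8.28 and 65.7 on the ovarian arrays. On the LCM cancer arrays it was 23.8 and 27.0, lower than on the LCM healthy arrays, at 46.1 and 32.9. The labels state that ovarian arrays served to compare captured and bulk tissue with the pancreas; captured ovarian tissue was not analysed here.

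**Figure D1:**
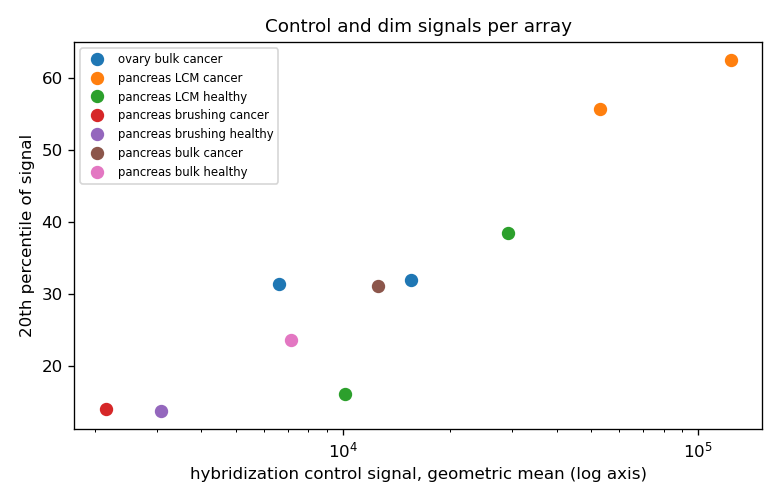
Each point is 1 array. The x axis is the geometric mean signal of the hybridization controls on a log axis and the y axis is the 20th percentile of signal, both in deposited signal units. The LCM cancer arrays lie highest on both axes, at 53110 and 123700 for the controls.

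In captured cancer against captured healthy tissue, 14 of 37 genes of the fibroblast and its matrix rose, and 7 of 20 of the ductal epithelium and 8 of 20 of the immediate early response fell. Camera with its preset correlation called all 3 lists and with an estimated correlation none (adjusted p = 0.251, 0.251 and 0.303 with an estimated correlation). For the ductal list the loss can come from the few arrays, as its estimated correlation of -0.0416 lay below the preset. For the fibroblast and matrix and immediate early lists the estimate was 0.0541 and 0.173, above the preset. Correlation can add to the loss for those lists. COL11A1, a fibrillar collagen, was 90.1-fold higher (log2 fold change 6.49 ± 0.67, SE, n = 2 against 2, adjusted p = 0.00107 by limma). Its 2 other probe sets were higher by 2.31 and 3.69 on the log2 scale. CRP, an acute phase protein, fell by 7.51 on the log2 scale (SE 0.67, adjusted p = 0.000612 by limma). The cancer signals of CRP, 18.4 and 79.5, lie near the 20th percentile of their arrays. They lay below 55.7 on replicate 1 and above 62.5 on replicate 2, so the size is approximate. The other probe set of CRP stood at -0.419. Of the 24 genes with the highest and lowest fold changes, 11 had at least 1 array of the dimmer group at or under its 20th percentile, and their sizes are approximate; for ST8SIA2, KIF4A and FOS both arrays were. Of 14570 genes, 48 rose and 214 fell. Without regard to the threshold, 3715 genes were at least 2-fold higher and 3095 lower, and 1085 and 951 at least 4-fold. With the mean of probe sets 41 rose and 58 fell.

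The genes with the highest fold changes included several of connective tissue. MCEMP1, a membrane protein of mast cells, rose by 7.29, LRRC15, a membrane protein of fibroblasts, by 5.65, PRRX1, a mesenchymal transcription factor, by 4.71, FBLN2, a matrix glycoprotein, by 4.65, and SFRP2, a secreted Wnt modulator, by 4.53 on the log2 scale. ST8SIA2, a sialyltransferase, rose by about 5.06 and KIF4A, a mitotic kinesin, by about 4.46, against healthy signals of 1.60 and 12.1 and of 3.49 and 11.5, all under the 20th percentile of their arrays. LINC02086, EPHA1-AS1, IGFL2 and BTBD18 rose by 4.95, 4.50, 4.46 and 4.38. Other probe sets gave smaller rises: 1.57 for LRRC15, 3.4 for SFRP2, 0.532 for ST8SIA2, 0.672 and 2.18 for PRRX1, and 1.84 for EPHA1-AS1. Of 37 measured members of the fibroblast and extracellular matrix list, 14 rose, 0 fell and the rest did not pass; 22 were higher and 2 lower when adjusted over the list alone. POSTN rose by 4.16, COL6A3 by 4.12 and COL1A2 by 4.12. The list's median was 2.21 (camera adjusted p = 3.65e-14; adjusted p = 0.251 with an estimated correlation). Among 10000 random lists matched on the LCM healthy level it stood at percentile 100.

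Among the genes with the lowest fold changes, ATF3, FOSB and FOS, transcription factors of the immediate early response, fell by 7.14, 6.09 and 5.42 on the log2 scale. CCDC198 fell by 6.94, OLFM4, a secreted glycoprotein of gut epithelium, by 6.84, C6, a complement component, by 6.24, and SPINK1, a trypsin inhibitor, by 6.08. GPRC5B fell by 5.82, VNN1, a pantetheinase, by 5.23, CFTR, the chloride channel of duct cells, by 5.13, and LGALS2 by 5.11. Other probe sets did not all share the sign: 2 of 5 for CFTR, 1 of 3 for GPRC5B and 1 of 2 for ATF3 did. Those of VNN1 and CCDC198 shared it with smaller falls, at -2.61 for VNN1 and -2.14 and -0.575 for CCDC198. Of 20 immediate early genes 8 fell and 0 rose, with 14 lower when adjusted over the list alone; DUSP1 fell by 4.49. The list's median was -2.34 (camera adjusted p = 1.24e-11; adjusted p = 0.303 with an estimated correlation). Of 20 ductal epithelium genes 7 fell and 0 rose, with 2 higher and 13 lower when adjusted over the list alone. KRT19, a keratin of duct cells, fell by 4.29, SCTR, the secretin receptor, fell by 4.73, and CDH1, the epithelial cadherin, fell by 3.70. The ductal median was -1.93 (camera adjusted p = 4.74e-08; adjusted p = 0.251 with an estimated correlation). Against level-matched random lists the immediate early and ductal medians stood at percentiles 0 and 0.02.

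Lists of several other cell types, most of them dim on the LCM healthy arrays, had positive medians in captured cancer. The islet list had a median of 1.74 with 0 of 16 members past the threshold (5 higher when adjusted over the list alone; camera adjusted p = 3.69e-05; adjusted p = 0.506 with an estimated correlation). The cell cycle list had a median of 1.49 and 1 of 26 members higher, CENPF, by 3.35 (6 higher when adjusted over the list alone; camera adjusted p = 1.36e-05; adjusted p = 0.251 with an estimated correlation). The lymphocyte median was 0.91 with 0 of 21 past the threshold, also when adjusted over the list alone (camera adjusted p = 0.019; adjusted p = 0.535 with an estimated correlation). The adipocyte median was 1.65, with CFD higher by 3.80 (1 of 8, and 2 when adjusted over the list alone; camera adjusted p = 0.00497; adjusted p = 0.303 with an estimated correlation). Against random lists matched on the LCM healthy level, these 4 medians stood at percentiles 34.72, 97.37, 67.18 and 88.85, none above the upper bound of those lists. The myeloid list, with a median of 1.47 and MRC1 higher by 3.36 (1 of 18, and 4 when adjusted over the list alone), stood at percentile 99.99 (camera adjusted p = 0.000218; adjusted p = 0.36 with an estimated correlation).

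Of the tumour epithelium list, 1 of 33 members rose and 4 fell, with 2 higher and 6 lower when adjusted over the list alone. PSCA, a surface antigen, rose by 3.60, and GABRP, SERPINB5 and LAMB3 fell by 5.0, 3.04 and 2.79. Its median was -0.78, at percentile 39.62 of level-matched lists (camera adjusted p = 0.0288; adjusted p = 0.321 with an estimated correlation). The list's median level was 12.58 and 12.70 on the LCM healthy arrays and 11.63 and 11.94 on the LCM cancer arrays. The arrays labelled healthy thus held these transcripts too. The endoplasmic reticulum folding list had a median of -1.19 with 1 of 24 lower, SPCS1, by 2.63 (3 when adjusted over the list alone; camera adjusted p = 8e-05; adjusted p = 0.251 with an estimated correlation). The MAPK output list had a median of -1.25 with 2 of 18 lower, of which HBEGF fell by 2.97, with 1 of 3 other probe sets of its sign, and MET fell by 2.69 but as a mean of its probe sets stood at 0.07 (5 when adjusted over the list alone; camera adjusted p = 0.00173; adjusted p = 0.36 with an estimated correlation). The oxidative phosphorylation list had a median of -0.89 with 1 of 28 lower, ATP5F1A, by 2.92 (2 when adjusted over the list alone; camera adjusted p = 0.000717; adjusted p = 0.303 with an estimated correlation); level-matched lists placed it at percentile 63.8. The MAPK output and folding lists stood at percentiles 0.19 and 2.5. The acinar list did not pass (adjusted p = 0.726; median 0.76), while 3 of its 20 members fell, SPINK1, REG1A by 4.85 and PRSS2 by 2.80. Of 27 cytosolic ribosomal protein genes 5 fell, RPL3 by 2.80 among them, with 1 higher and 7 lower when adjusted over the list alone. PFKFB3 of the glycolysis and hypoxia list fell by 2.35, and PRRX1 was the 1 of 12 mesenchymal transition genes that rose. Adjusted p was 0.356 for endothelium, mesothelium and ovary, and glycolysis and hypoxia, 0.0933 for mast cell and cytosolic ribosomal protein, 0.233 for Schwann cell, 0.522 for red blood cell, intestinal epithelium and interferon response, 0.228 for smooth muscle and 0.187 for mesenchymal transition. Of these, mesenchymal transition stood at percentile 99.21, glycolysis and hypoxia at 97.93 and intestinal epithelium at 2.1 of level-matched lists.

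The count of 262 genes rested on which pair of arrays set the spread. Without LCM healthy replicate 1 or 2 no gene passed, without LCM cancer replicate 1 or 2 there were 1971 and 1020, after quantile normalization 71 and without the variance trend 0. The median over all genes was 0.08 as deposited, -0.13 after quantile normalization, when 20 rose and 51 fell, and -0.87 after median centring, when 22 rose and 869 fell.

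**Figure D2:**
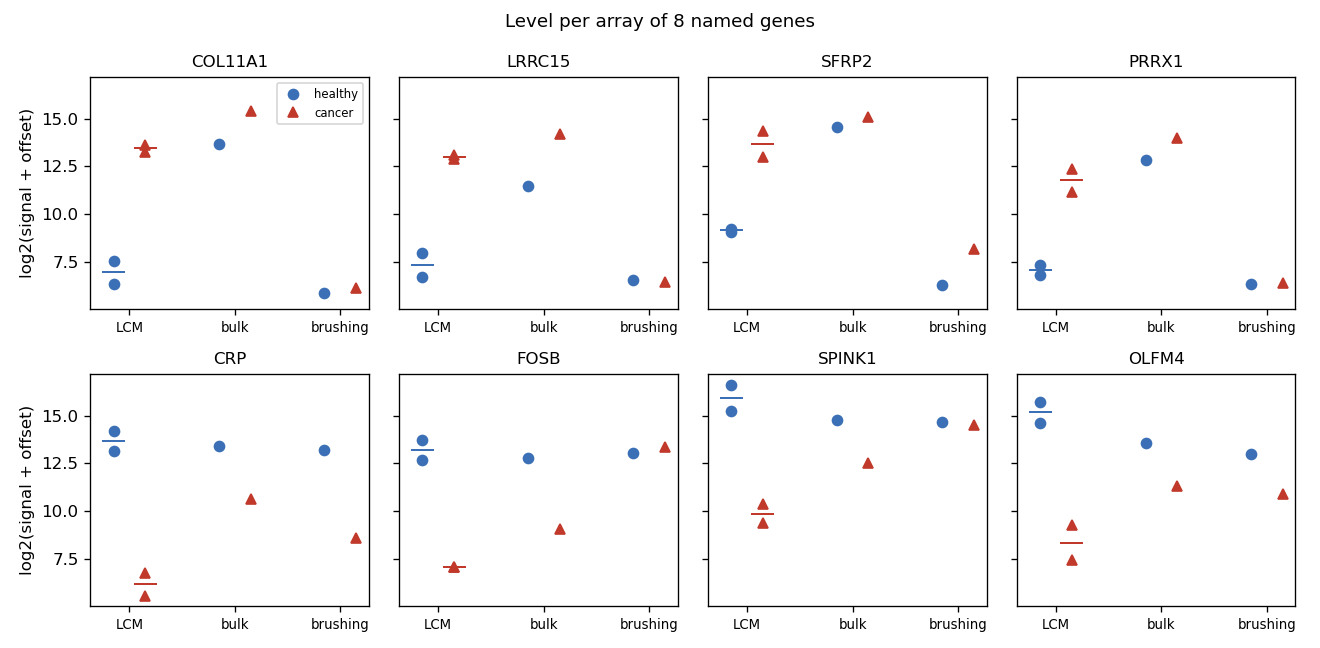
Each point is 1 array and the y axis is log2 of signal plus offset; circles are healthy, triangles are cancer, and short lines are means of 2 arrays. COL11A1 differed by 6.49 between the LCM groups, and CRP was lower in cancer in all 3 preparations.

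In bulk tissue, with 1 array per group and no replicate check, 17 of 20 acinar genes were higher in the cancer array and 18 of 20 immediate early genes were lower. CELA3A and CELA3B, elastases of acinar cells, were higher by 5.79 and 4.29 on the log2 scale, and REG1B by 4.48. PSCA, KRT20 and MUC16, a mucin, were higher by 4.07, 4.06 and 3.93. LINC02086, STYXL2, SPRR3, CUEDC1 and IL2RA, a cytokine receptor chain, were higher by 4.77, 3.57, 3.40, 3.36 and 3.35. The other probe set of IL2RA and that of INTS14 had the opposite sign, as did 1 of 2 for RGS1 and ATF3 and 2 of 3 for ZFP28. FOSB was lower, at -3.72, as were RGS1 at -3.52, IAPP, a peptide of islet beta cells, at -3.41, and IL6, a cytokine, at -3.21. INTS14, PTX3, CD14, CLDN2, ATF3, CRP, ZFP28 and SST stood at -3.17, -3.02, -2.94, -2.92, -2.81, -2.78, -2.70 and -2.68. For 7 of the 24 genes named by size, CELA3A, CELA3B, KRT20, LINC02086, CUEDC1, IL2RA and ZFP28, the dimmer array was at or under its 20th percentile, so their sizes and order are approximate. In all, 139 genes were at least 4-fold higher and 53 at least 4-fold lower; the split was 93 and 84 after quantile normalization and 69 and 144 after median centring. The acinar median was 1.03, at percentile 100 of 10000 random lists matched on mean signal, and the tumour epithelium median 0.74, also at percentile 100. The immediate early, myeloid and islet medians were -1.20, -0.82 and -0.78, all at percentile 0. The interferon response median was 0.30, at percentile 97.75. The intestinal epithelium median of 4 genes was 1.4, at percentile 99.82.

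In duct brushings, also 1 array per group, 346 genes were at least 4-fold lower in the cancer array and 120 at least 4-fold higher. CRISP3, a secreted protein, stood at -6.85, CES1, a carboxylesterase, at -6.61, CEACAM7 at -5.67, ANXA13 at -5.63 and LGALS2 at -5.49. The cancer signal of CES1 was 6.57, under the 20th percentile of that array, so its size and place are approximate. MOGAT1, GALNT14, REG3A, ABCB1, RELN, SLC28A2 and CRP stood at -5.37, -5.25, -5.15, -4.81, -4.77, -4.71 and -4.61. FAM20A was higher by 5.4, SPRED1, an inhibitor of MAPK signalling, by 4.30, LMO3 by 3.83, VGLL3 by 3.67 and IRX3, a homeobox factor, by 3.61. ALDH1A3, CST4, LTBP2, SPOCK3, CDH11, SOX5 and H2AJ were higher by 3.56, 3.38, 3.03, 3.01, 3.0, 3.0 and 2.98. The cancer signal of MOGAT1, 14.2, and the healthy signals of CDH11 and CST4, 16.4 and 24.3, lay under the offset of 28.84. Their sizes are approximate too, though each signal lay above the 20th percentile of its array. The fibroblast and matrix median was 1.05, at percentile 100 of the random lists, and the intestinal epithelium median of 4 genes was -3.46, at percentile 0.01. The immediate early median was -0.19, at percentile 8.07, with 9 of 20 members higher and 11 lower. The other probe set of REG3A had the opposite sign, as did 1 of 2 for SPRED1, 1 of 3 for LMO3 and SOX5 and 2 of 3 for H2AJ. The ductal and tumour epithelium medians were -0.47 and -0.43, at percentiles 0.16 and 0.05.

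**Figure D3:**
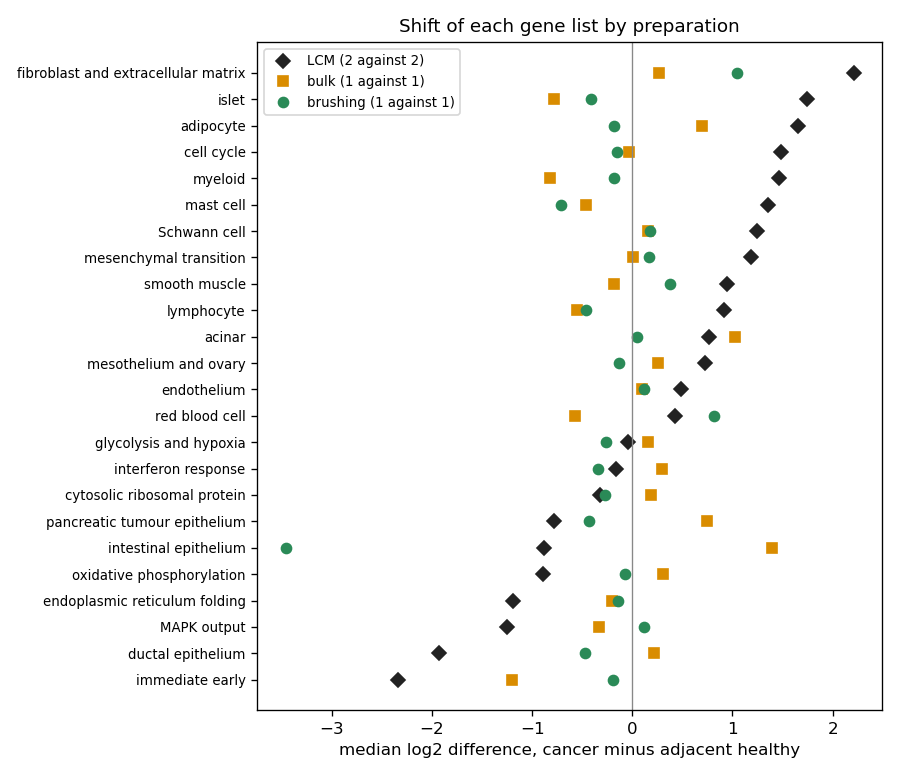
Each row is a gene list and the x axis is the median log2 difference of its members, cancer minus adjacent healthy; diamonds are LCM, squares bulk and circles brushing. The fibroblast and matrix list was above 0 in each, at 2.21, 0.26 and 1.05.

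Across the 3 preparations together, 6 genes differed between cancer and healthy arrays. CRP fell by 5.60 on the log2 scale (SE 0.69, adjusted p = 0.0194 by limma). Its other probe set stood at -1.35. CLDN2, a claudin of leaky epithelia, SERPINA3, an acute phase protease inhibitor, CXCL1, a neutrophil chemokine, and HBEGF, a growth factor, fell by 3.58, 3.52, 3.13 and 2.44. IRX3 rose by 3.34 (SE 0.52, adjusted p = 0.0476). Each had the same sign in every preparation, and 1 of 3 other probe sets of HBEGF shared its sign. With the preset correlation 8 of 24 lists passed. The fibroblast and matrix median was 1.49 (camera adjusted p = 1.59e-14; adjusted p = 0.63 with an estimated correlation), with 0 of 37 past the threshold and 22 higher and 2 lower when adjusted over the list alone. The immediate early median was -1.46 (camera adjusted p = 2.06e-10; adjusted p = 0.63 with an estimated correlation), with 0 of 20 past the threshold and 12 lower when adjusted over the list alone; by preparation the medians were -2.34 in LCM, -1.20 in bulk and -0.19 in brushing. No gene passed without the LCM arrays, after quantile normalization or median centring, without an offset, the variance trend or the preparation term, or with a stricter filter or the noise floor; nor did any without LCM cancer replicate 1 or LCM healthy replicate 1 or 2. There were 79 and 77 without the bulk cancer or bulk healthy array and 29 without either brushing array; the mean of probe sets gave 1 and all probe sets 31.

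The cancer effects of the preparations were weakly related across genes, which are not independent replicates. Pearson's r was 0.243 for LCM and bulk, 0.169 for LCM and brushing and 0.031 for bulk and brushing over 14570 genes, and Spearman's rho was 0.251, 0.138 and 0.0387. With single pairs of LCM arrays Pearson's r ranged from 0.14 to 0.252 for LCM and bulk and from 0.0843 to 0.216 for LCM and brushing, so their order is not separated. Of the 48 genes higher in captured cancer, 42 were also higher in bulk cancer (87.5%, against 39.6% to 66.7% for genes matched on mean level) and 35 in the cancer brushing (72.9%, against 39.6% to 66.7%). The matching used the mean over all arrays, not the healthy level. The 20th percentile of signal was high on LCM cancer, at 55.7 and 62.5, and higher on bulk cancer than bulk healthy, at 31.2 and 23.6. Raised dim signals could thus give a part of the agreement of the higher genes with bulk. Of the 214 lower genes, 155 were lower in bulk (72.4%, against 42.5% to 55.6%) and 172 in the brushing (80.4%, against 39.3% to 52.3%).

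In captured tissue against bulk tissue, 7 of 16 islet genes and 5 of 37 fibroblast and matrix genes fell. GCG and SST, hormones of islet alpha and delta cells, fell by 7.09 and 5.51 on the log2 scale (SE 0.94 and 0.74), INS, insulin, by 4.90, and SCG5 and CHGB, secretory granule proteins, by 5.68 and 5.34. ABCC8, the sulfonylurea receptor, SLC30A8, the granule zinc transporter, and GAD2 fell by 7.08, 5.92 and 4.90, though none of their other probe sets shared the sign. SLC16A10, GPNMB, S100B and ABCA8 fell by 5.22, 4.72, 4.30 and 4.29; the other probe set of S100B and 1 of 2 for SLC16A10 and ABCA8 had the opposite sign. Of 16 genes with the highest and lowest fold changes, 9 had an array of the dimmer group at or under its 20th percentile. DNAJB2, CXCL17, a mucosal chemokine, and PTK6, an epithelial kinase, rose by 3.52, 3.20 and 2.51. Of 14570 genes 4 rose and 50 fell (limma, n = 4 against 2), and 11 of 24 lists passed with the preset correlation. Of 16 islet genes 7 fell and 0 rose, with 13 lower when adjusted over the list alone (median -3.98; camera adjusted p = 4.69e-16; adjusted p = 0.294 with an estimated correlation). Of 37 fibroblast and matrix genes 5 fell, INHBA by 3.76 and COL8A1 by 3.58 among them, with 1 higher and 25 lower when adjusted over the list alone (median -2.26; camera adjusted p = 3.77e-18; adjusted p = 0.294 with an estimated correlation). The count was 11 after quantile normalization, 83 after median centring and 3 without an offset. It was 0 without LCM healthy replicate 1 or the bulk healthy array, 9 without LCM healthy replicate 2, 6 without the bulk cancer array, 88 without either brushing array, 207 without LCM cancer replicate 2, and 329 without both LCM cancer arrays, a setting chosen after the data were seen.

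In duct brushings against bulk tissue, 29 of 37 fibroblast and matrix genes fell; the ACTB ratio was higher on both brushing arrays, at 69.8 and 105.9, than on bulk, at 27.3 and 33.6. COL11A1, COL5A1, COL10A1 and COL5A2, collagens, fell by 8.52, 7.56, 6.89 and 6.83 on the log2 scale (SE 1.22, 0.62, 0.61 and 0.69), and AEBP1, SFRP2, POSTN, PRRX1, ADAMTS2 and THBS2 by 7.94, 7.61, 7.13, 7.05, 6.75 and 6.66. ABCC8 and SLC30A8 fell by 8.0 and 7.66. HINT3 rose by 4.69, MYBPC1 by 3.97, PGC, a pepsinogen, by 3.81, and GALNT3, RHPN2 and TMPRSS2, a serine protease of epithelia, by 3.42, 3.42 and 3.33. SOX9 and ONECUT2, transcription factors of duct cells, rose by 3.25 and 3.21, and OR7E14P, TC2N, FOXA3 and PLS1 by 3.42, 3.18, 3.13 and 3.13. The opposite sign was seen for 2 of 3 other probe sets of TMPRSS2, 1 of 2 of ADAMTS2 and 1 of 4 of ONECUT2. Of 24 genes with the highest and lowest fold changes, 2, ABCC8 and ADAMTS2, had a brushing array at or under its 20th percentile. That percentile, 14.0 and 13.8 on the cancer and healthy brushings, lay under the offset of 28.84. The brushing signals of SLC30A8, 26.3 and 27.5, and the lower one of AEBP1, 27.4, also lay under the offset. Those of COL11A1, 29.2 and 42, lay above it but near it. The sizes for these genes are approximate. SOX9 and ONECUT2 were the 2 of 20 ductal genes that rose, with 4 when adjusted over the list alone (median 1.29; camera adjusted p = 7.88e-06; adjusted p = 0.336 with an estimated correlation). Of 14570 genes 50 rose and 491 fell (limma, n = 2 against 2). Of 37 fibroblast and matrix genes 29 fell and 0 rose, with 33 lower when adjusted over the list alone (median -5.60; camera adjusted p = 4.13e-42; adjusted p = 0.0596 with an estimated correlation). Of 16 islet genes 13 fell, with 14 lower when adjusted over the list alone (median -5.62; camera adjusted p = 3e-16; adjusted p = 0.234 with an estimated correlation). Of 16 endothelial genes 6 fell, VWF by 5.17 and ROBO4 by 4.63, with 10 lower when adjusted over the list alone (median -2.75; camera adjusted p = 1.95e-08; adjusted p = 0.0596 with an estimated correlation). Quantile normalization gave 144 genes in place of 541 and median centring 176, with the median over all genes at -0.27 as deposited and 0.01 and 0.41 after them. The count was 59 and 223 without the bulk healthy or bulk cancer array, 118 without the brushing cancer array, 1027 without LCM cancer replicate 2 and 1527 without both LCM cancer arrays, again chosen after the data were seen.

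In captured tissue against brushings, 19 of 37 fibroblast and matrix genes rose. The ACTB ratio was lower on every LCM array, at most 46.1, but the GAPDH ratio did not separate the groups. The GAPDH ratio was 46.9 and 14.6 on LCM cancer, 20.4 and 16.2 on LCM healthy, and 22.4 and 19.3 on the cancer and healthy brushings. KIAA1755, AEBP1, COL5A1, THBS2, CLEC11A, COL1A2 and SCUBE2 rose by 4.71, 4.68, 4.65, 4.63, 4.63, 4.62 and 4.58 on the log2 scale, with SE between 0.54 and 0.72. The brushing signals of KIAA1755 were 2.83 and 2.85, under the 20th percentile of their arrays, so its size and place are approximate. In all, 3 of 17 genes, with SCUBE2 and ADGRG2, had such an array in the dimmer group. The lower brushing signal of AEBP1, 27.4, lay under the offset of 28.84, so its size is approximate too. TCF4, IGFBP5, CTHRC1, SFRP2 and COL6A3 rose by 4.32, 4.21, 4.2, 4.19 and 4.15. S100A8, a neutrophil protein, ADGRG2, PTGR1, HINT3 and RPF1 fell by 4.42, 3.88, 3.59, 3.23 and 2.75; for PTGR1 and RPF1 no other probe set shared the sign, for HINT3 1 of 2 did, and RPF1 as a mean of its probe sets stood at 0.11. Of 14570 genes 121 rose and 5 fell (limma, n = 4 against 2). Of 37 fibroblast and matrix genes 19 rose, with 30 higher when adjusted over the list alone (median 3.06; camera adjusted p = 3.48e-20; adjusted p = 0.269 with an estimated correlation). The median over all genes was 0.32 as deposited and -0.86 after median centring, when 0 genes passed; quantile normalization gave 10 and no offset 196. Leaving out the brushing cancer array gave 0 and the brushing healthy array 46, leaving out LCM cancer replicate 1 gave 35 and replicate 2 gave 312, either LCM healthy array 36, and both LCM cancer arrays, a setting chosen after the data were seen, 22.

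The difference of the cancer effect between LCM and bulk was tested gene by gene, and 0 genes passed in limma, with 501 at an unadjusted p under 0.05. The highest statistics belonged to MCEMP1 at 6.51, COL11A1 at 4.79, FBLN2 at 6.41, CCL18, a macrophage chemokine, at 5.43 and COL1A2 at 3.47, given as values. The lowest belonged to CCDC198 at -7.35, GPRC5B at -6.13, C6 at -7.17, CFTR at -5.67 and KRT19 at -5.09, with a smallest adjusted p of 0.123 for CCDC198. Other probe sets of the same sign were 1 of 2 for CCDC198, 2 of 3 for GPRC5B and 2 of 5 for CFTR. The bulk side has 1 array per group. Without LCM cancer replicate 1 or 2 the count was 362 and 106. The median over all genes was -0.07 as deposited, -0.19 after quantile normalization and -0.67 after median centring.

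In bulk ovarian cancer against the 1 bulk pancreatic cancer array, 5 of 33 tumour epithelium genes fell; the single array is assumed to vary like the replicated ones. CEACAM6, a surface antigen, and CTSE, a gastric protease, fell by 8.20 and 8.01 on the log2 scale (SE 0.95 and 1.17), CFTR by 7.55 and TFF1, a mucosal peptide, by 6.83. SPRR1A, MCEMP1, ANXA10, PIGR, the receptor that carries IgA across epithelium, and GPX2 fell by 7.09, 6.92, 6.89, 6.85 and 6.84, and the islet genes ABCC8 and GCG by 7.56 and 7.18; the other probe set of ABCC8 and 2 of 5 of CFTR had the opposite sign. Of 11 genes named, 6 had an ovarian array at or under its 20th percentile. Ovarian replicate 1 is the array with the low GAPDH ratio, and the ovarian arrays were unlike each other. Across genes, Pearson's r of levels between them was 0.655. Replicate 2 had a higher r with bulk pancreatic cancer, 0.786, and replicate 1 with LCM healthy replicate 1, 0.693. Of 14570 genes 0 rose and 28 fell (limma, n = 2 against 1, with 765 at an unadjusted p under 0.05). Of 33 tumour epithelium genes 5 fell, S100P by 6.45 among them, with 20 lower when adjusted over the list alone (median -3.41; camera adjusted p = 3.53e-26; adjusted p = 0.129 with an estimated correlation). The mesothelium and ovary list had a median of 1.83 with 0 of 17 past the threshold and 6 higher when adjusted over the list alone (camera adjusted p = 5.81e-10; adjusted p = 0.129 with an estimated correlation). Without LCM healthy replicate 1 or 2, which help to set the spread, no gene passed; without ovarian replicate 2 there were 112, and after quantile normalization or without an offset 17.

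The median, the mean and the test of a list differed in sign in few cases, none of which passed. For interferon response in captured cancer the median was -0.17, the mean 0.17 and the test upward, and over the 3 preparations they were -0.05, 0.095 and upward. For LCM against bulk this held for the intestinal epithelium and immediate early lists, for brushing against bulk for intestinal epithelium, glycolysis and hypoxia, folding, interferon response and oxidative phosphorylation, and for LCM against brushing for tumour epithelium, intestinal epithelium, glycolysis and hypoxia and interferon response. It also held for mesothelium and ovary in the difference of effects and for folding and cytosolic ribosomal protein in the ovarian comparison.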

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

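The test of the lower genes in the brushing pair and that of the epithelial lists were chosen after the result was seen.

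For the difference of the cancer effect between LCM and bulk, 14 gene lists passed camera with the preset correlation and 0 with an estimated one. The bulk side is 1 array per group, 0 genes passed and simulated changes were recovered at 0%, so a difference is not established. The median differences, LCM minus bulk, were 3.04 for islet, 2.19 for myeloid, 1.83 for fibroblast and matrix, 1.72 for lymphocyte, 1.67 for mast cell and 1.51 for cell cycle. They were -3.02 for intestinal epithelium, -2.52 for ductal epithelium, -1.64 for tumour epithelium, -1.06 for endoplasmic reticulum folding, -1.05 for oxidative phosphorylation, -0.991 for acinar, -0.947 for immediate early and -0.673 for cytosolic ribosomal protein. A control transcript outside the comparisons, dap, which is added to RNA before labelling in some protocols, had a signal of 1772 on ovarian replicate 1 and at most 58.2 on the other arrays. No group held 4 or more arrays, so no array was tested as an outlier within its group.

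Over all genes in captured cancer, 3715 were at least 2-fold higher and 3095 at least 2-fold lower. With the mean of probe sets 41 genes were called higher and 58 lower. Among the genes called in the main fit, more were lower than higher on the LCM cancer arrays. Loss of signal on those arrays alone is argued against as the cause of all of it, since 80.4% of the lower genes were also lower in the brushing pair, above 52.3%, the upper bound of genes matched on mean level; but the median difference there was -0.49, 62 of 214 were at least 2-fold lower, and the median of the same genes in LCM was -3.38, so a part stays open. A smaller share of epithelial cells in the captured cancer stays open: the ductal list lay below the 2.5th percentile of level-matched lists, at 0.02, and the tumour epithelium list did not, at 39.62, so 1 of 2 lists met the prediction. A first form of that test was dropped because its limit had been set at a value already seen, and a change within the cancer cells was not tested.

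Lists of dim genes had positive medians in captured cancer. Raised dim signals on the LCM cancer arrays are a candidate explanation for most of them: of the islet, lymphocyte, myeloid, adipocyte and cell cycle lists, 1 of 5, myeloid, lay above the upper bound of lists matched on the LCM healthy level. The same explanation is argued against for the fibroblast and matrix list, at percentile 100, with a median of 2.21 against an upper bound of 0.26. Which cells were captured is not stated, so a difference in captured stroma stays open as a hypothesis.

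For the 6 genes called over the 3 preparations, other splits of the arrays were counted. Of the 34 splits of the 8 arrays that could be fitted, 3 gave as many genes, the real one included, and the highest other split gave 1173. The other 31 gave 0. The count of 1173 came from the 2 splits that set the LCM cancer pair against the LCM healthy pair while keeping each other preparation whole. With preparation in the fit, their estimate is the LCM difference, which points to a structure of the samples. Their fit takes the cancer and healthy arrays of bulk and of brushing as replicates. Its spread thus differs from that behind the 262 genes of the LCM comparison. Those 2 hold the LCM difference itself, so the count of splits does not decide whether chance can be excluded. A split of LCM against the rest could not be fitted beside preparation.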

How the results depend on the processing

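Array weights, a common noise floor and fits without both LCM cancer arrays were chosen after the data were seen. Of 3535 values of named genes under alternatives, 2398 kept their sign and their side of the threshold, 1092 lost the threshold, 18 gained it, 25 moved beyond the spread and 2 changed sign. Both sign changes came from the mean over probe sets, which set MET in captured cancer at 0.074 and RPF1 in LCM against brushing at 0.109; their probe sets differ in sign. Under the scalings 0 named genes changed sign. Of 702 list values 579 kept their side, 123 lost the threshold and 0 changed sign. With an estimated correlation, where the test rests on few residual degrees of freedom, 0 of 78 list shifts passed. The cause was not tested unless stated.

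The counts were 262 for captured cancer, 6 over the 3 preparations, 54 for LCM against bulk, 541 for brushing against bulk, 126 for LCM against brushing, 28 for ovary, and 192 and 466 at least 4-fold for cancer against adjacent healthy, bulk, and cancer against adjacent healthy, brushing. In that order, leaving out those within 1.5 times, quantile normalization gave 71, 0, 11, 144, 10 and 17 for the tested comparisons. Median centring gave 891, 0, 83, 176 and 0 before ovary. Without an offset there were 174, 0 and 3, then 196 for LCM against brushing, 17 for ovary, 492 in bulk and 977 in brushing. The mean of probe sets gave 99, 1, 3, 347, 76, 1, 121 and 247. All probe sets, a larger number of tests, gave 439, 31, 135, then 292 for LCM against brushing, 474 in bulk and 1128 in brushing. Without the variance trend there were 0, 0 and 15, then 13 for LCM against brushing and 0 for ovary. The noise floor gave 0, 0, 1, 109, 0 and 0. A stricter filter gave 0 over the 3 preparations, 5 for LCM against bulk and 90 in bulk; no filter gave 371 in bulk. A double offset gave 107 for LCM against bulk and 95 in bulk.

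For captured cancer, all 10 arrays in the fit gave 47, array weights 562 and a replicate block over the numbered pairs 1059, though the numbers are not shown to pair arrays. With the noise floor all 262 genes kept their sign, their median absolute log2 fold change went from 3.42 to 3.16 and their median SE from 0.603 to 0.467. The prior degrees of freedom went from 9.68 to 1.91 and the count to 0; the cause was not tested. Over the 3 preparations the count was 0 with no preparation term, 0 without the LCM arrays, 85 without the bulk arrays and 34 without the brushing arrays. Without both LCM cancer arrays it was 329 for LCM against bulk, 22 for LCM against brushing and 1527 for brushing against bulk. Pearson's r of LCM and bulk was 0.17 after quantile normalization against 0.243. Its spread was taken over pairs of LCM arrays, and that for bulk and brushing from the smaller of those, as no replicates exist.

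With 1 array left out the count ranged from 0 to 1971 for captured cancer, 0 to 79 over the 3 preparations, 0 to 207 for LCM against bulk, 59 to 1027 for brushing against bulk, 0 to 312 for LCM against brushing, 0 to 362 for the difference of effects and 0 to 112 for ovary. With fewer arrays, the spread rests on the replicates that remain, and a lone array is assumed to vary like the others. Signal over background limits dim genes, whose fold changes the offset shrinks. On the brushing arrays 31.6% and 31.4% of signals lay under the offset, and on the LCM cancer arrays 9.30% and 5.42%.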

Other observations

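The test in this part was chosen after the result was seen. List levels are compared here between arrays, on the same probe sets. The median level of 20 acinar genes was 7.17 on the bulk healthy array and 8.83 on the bulk cancer array, 7.09 and 8.30 on the LCM healthy arrays and 8.78 and 8.94 on the LCM cancer arrays. SPINK1 stood at 14.74 and REG1A at 12.09 on the bulk healthy array, though levels of different probe sets are not comparable. The tumour epithelium median was 12.58 and 12.70 on the LCM healthy arrays, 11.63 and 11.94 on the LCM cancer arrays, 12.87 and 12.29 on the healthy and cancer brushings, and 10.84 and 11.69 on the healthy and cancer bulk arrays. On the ovarian arrays it was 8.94 and 7.62.

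A swap of the labels of the bulk pair could give the higher acinar level of the bulk cancer array. Of the genes higher in captured cancer, 87.5% were also higher in the array labelled bulk cancer. This lay above 66.7%, the upper bound of genes matched on mean level. The median difference was 0.63, and 13 of 48 were at least 2-fold higher. But the 20th percentile of signal was also higher on the bulk cancer array, at 31.2, than on bulk healthy, at 23.6. Raised dim signals on both kinds of cancer array could give the same agreement, so the test does not decide on a swap. Tumour cells in the adjacent tissue were not tested and stay open. Every difference between cancer and healthy arrays is therefore relative to adjacent tissue whose cell make-up is not known.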
